A study of Mus musculus with 12 samples.

How the data were processed

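Gene expression was measured by RNA sequencing in the tibialis anterior muscle of wild-type (WT), mdx and DMD-Null mice, in 12 libraries with 4 per genotype. Per the labels, RNA was isolated with an Agilent kit, its integrity number was above 7, and poly(A) RNA went into stranded TruSeq libraries. Per the submitters' processing notes, the tools were cutadapt 1.10, FastQC 0.10.1, HISAT2 2.0 and StringTie 1.3.4. The table that the authors deposited holds whole-number read counts per gene and library, with no normalization. Beside them it holds FPKM values, which the authors scaled to gene length and library size and deposited for the same genes. How the counts were derived, and whether counting used the strand, is not given in the sources used here. Counts of paralogs, of overlapping genes and of genes with an antisense partner are therefore uncertain, as for the hemoglobin, Mup and ribosomal protein genes.

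The table held 30239 genes. The processing notes name GRCm39, but of the 30155 genes also present in the GRCm38 annotation, 99.70% shared their start or end with it, so positions are given as the deposited table gives them and are read as GRCm38. Gene symbols are those of the deposited table, where 58 names were carried by more than 1 gene identifier.

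Samples were grouped by the genotype in the labels. The labels number the replicates within each genotype, and nothing else says that they came from separate animals, so p-values measure the spread between these samples. No sequencing batch is named in the labels. The 3 comparisons were mdx against WT, DMD-Null against WT, and DMD-Null against mdx. The last of these also tests the difference between the effects of both mutants against WT.

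Genes entered the tests if FPKM was at least 1 in at least 4 libraries, which left 11376 genes and removed 18863. The plan named a limma fit of FPKM with edgeR on the counts in its place if the table held counts. It did, so the main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts with TMM factors, all 12 libraries in 1 model and no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The SE of an edgeR log2 fold change was derived as its absolute value over the square root of the test's F statistic. Dmd itself was under the filter, so its values come from the same edgeR test fitted without the filter. CPM (counts divided by the library total and multiplied by 1e6) were scaled by the TMM factors, with a prior count of 2 on the log2 scale. Sums over organ lists, and levels of liver genes among the flagged results, were left unscaled unless stated.

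Before the data were examined, 38 gene lists, the tests, the filter, the alternative settings and a rule for the genes to be named were fixed. The rule took, per comparison, Dmd and Utrn. From each of 8 lead lists it took the 2 members past the threshold with the largest change, or the most highly expressed member where none passed. From each other list with a significant list test it took 1 member. Over all genes with a mean FPKM of at least 5 in a group and no overlap between groups, it took the 5 largest rises and the 5 largest falls. Other genes are named as examples of their lists, or singly, and were chosen after their values were seen. Among the latter are Myog, Myh3, Pax7, the hemoglobin genes, Sftpc and Capn3.

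Of the 38 lists, 33 were fixed for testing and 31 had at least 5 tested members. These were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Camera compares the members of a list with all other tested genes, so its direction is relative to them. Camera with an estimated correlation and fry were the alternatives. Means over the 8 lead lists per library were compared by an exact two-sided permutation test of 4 against 4, with 70 arrangements and a smallest possible p of 0.0286. Further gene terms of 15 to 300 tested genes were tested with camera as well. To gauge what shared WT libraries give by chance, 12 unchanged libraries, WT included, were simulated 100 times. Each gene was drawn independently, so any structure among the real WT libraries is absent from the simulations.

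After the data were seen, further fits were added. One replaced TMM factors by offsets from a loess curve of each library's counts on gene GC content (span 0.5, degree 1), for which 99.9297% of the tested genes had a GC value. Others left out WT 1 and WT 3, or these and DMD-Null 4, or used library totals alone. Lists of genes typical of 8 other organs were written after liver and lung genes had been noticed. The alternative settings fixed beforehand were no filter, a mean FPKM of at least 5, median-of-ratios scaling, DESeq2 1.42.0, limma on log2(FPKM + 1) with pseudocounts of 0.1 and 0.5 in place of 1, TPM, quantile normalization, array weights, the 8 libraries of the groups compared, a replicate block and each replicate left out in turn.

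The edgeR and camera steps were tested on simulated counts of 11376 genes with 200 changed. For mdx against WT, DMD-Null against WT and DMD-Null against mdx, edgeR recovered 33%, 26.5% and 30.5% of 2-fold changes and 92%, 92% and 95% of 4-fold changes, with at most 10 false calls. It recovered 0% of 1.5-fold changes in each comparison. Total counts per library ranged from 60693078 to 68054627. Floors for genes without reads use 3 counts over a group and cover counting error only.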

Results

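Poly(A) RNA was sequenced from the tibialis anterior, a fast-twitch muscle of the lower leg, of untreated mice aged 6 months. The data comprised 12 libraries of 3 genotypes, 4 each. WT mice have an intact dystrophin gene, and mdx mice, the standard model of Duchenne muscular dystrophy, carry a nonsense mutation in it. DMD-Null mice are named for the loss of the gene, and the labels do not say how it was disrupted. Total counts were 61145904 to 63073041 in WT, 64120795 to 68054627 in mdx and 60693078 to 64554184 in DMD-Null, and 21533 to 23152 genes had reads in a library.

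Libraries of the same genotype resembled each other in mdx, where correlations of log2 CPM across genes were 0.981 to 0.988, and in DMD-Null (0.945 to 0.982). In WT they ranged from 0.866 to 0.980, because WT 1 and WT 3 were close to each other (0.980), WT 2 and WT 4 were close to each other (0.976), and the pairs stood apart. No pair of replicates differed by as little as sampling noise. The first principal component held 64.0% of the variance, with WT 1 at -98.4, WT 3 at -103, WT 2 at -4.05, WT 4 at -33.4, and the mdx libraries at 24.1 to 36.6. WT 1 and WT 3 held relatively more reads of GC-rich genes. Spearman's rho between a gene's GC content and its log2 ratio to the mean of all libraries, across genes, was 0.655 in WT 1, 0.604 in WT 3 and 0.449 in DMD-Null 4, against -0.579 to -0.0935 in the other 9. Mitochondrially encoded genes took 4.96% of the counts in WT 1 and 6.57% in WT 3, against 9.31% to 19.3% elsewhere. TMM factors were 0.694 and 0.698 in these libraries and 0.951 to 1.18 in the rest.

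**Figure D1:**
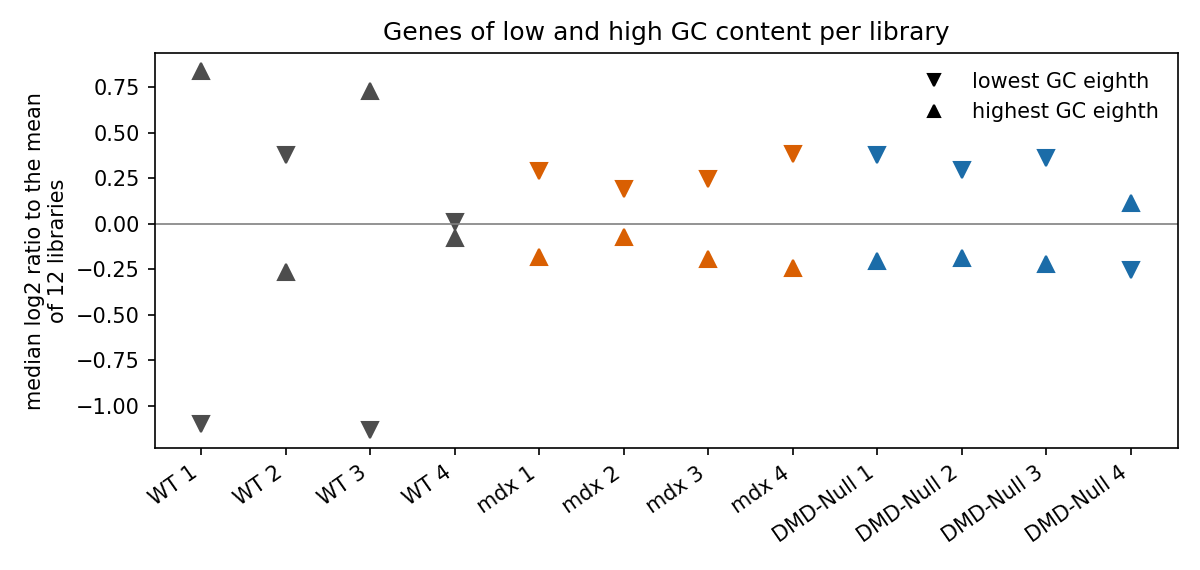
Median log2 ratio to the mean of the 12 libraries (y axis) in each library (x axis), for genes in the lowest and highest eighth of GC content. In WT 1 and WT 3 the genes of lowest GC content lie at -1.10 and -1.13 and those of highest GC content at 0.84 and 0.73, while DMD-Null 4 lies at -0.25 and 0.11.

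Dmd, which encodes dystrophin, the protein that links the cytoskeleton of the muscle fibre to the surrounding matrix, was read in each library first. The gene (ENSMUSG00000045103) lies on chromosome X from 82948870 to 85206141. Its counts were 542, 3597, 412 and 2446 in WT 1 to 4, 1062, 713, 869 and 1254 in mdx 1 to 4, and 164, 71, 111 and 114 in DMD-Null 1 to 4. All 4 DMD-Null libraries thus lay below the other 8, as their label requires, yet each held Dmd reads. Mean levels were 31.5 ± 25.2 CPM in WT, 13.6 ± 3.14 in mdx and 1.68 ± 0.597 in DMD-Null (SD, n = 4), so that WT exceeded DMD-Null 18.8 times and mdx exceeded it 8.11 times. Both differences had the smallest possible p of the exact permutation test, 0.0286, while mdx and WT did not differ (exact p = 0.371). In edgeR's quasi-likelihood test, Dmd fell in DMD-Null against WT with a log2 fold change of -4.22 (SE 0.57, edgeR adjusted p = 0.00056). The changes in mdx against WT of -1.20 (SE 0.50, edgeR adjusted p = 0.137) and in DMD-Null against mdx of -3.02 (SE 0.54, edgeR adjusted p = 0.388) did not pass. Both passed without WT 1 and WT 3, which had the lowest Dmd counts of WT, at -1.96 (edgeR adjusted p = 0.00179) and -3.02 (edgeR adjusted p = 0.00407). Without WT 2 the change in mdx against WT was -0.63.

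Utrn (ENSMUSG00000019820, chromosome 10 from 12382188 to 12868281) encodes utrophin, the closest relative of dystrophin. It stood at 18.2 ± 4.80 CPM in WT, 26.0 ± 3.16 in mdx and 23.2 ± 1.68 in DMD-Null (SD, n = 4). It rose in mdx by 0.51 on the log2 scale (edgeR adjusted p = 0.0451), a call that ended without WT 1 and WT 3 (0.19, edgeR adjusted p = 0.309). The change of 0.35 in DMD-Null did not pass (edgeR adjusted p = 0.155), nor did the difference between the mutants of -0.17 (edgeR adjusted p = 1).

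**Figure D2:**
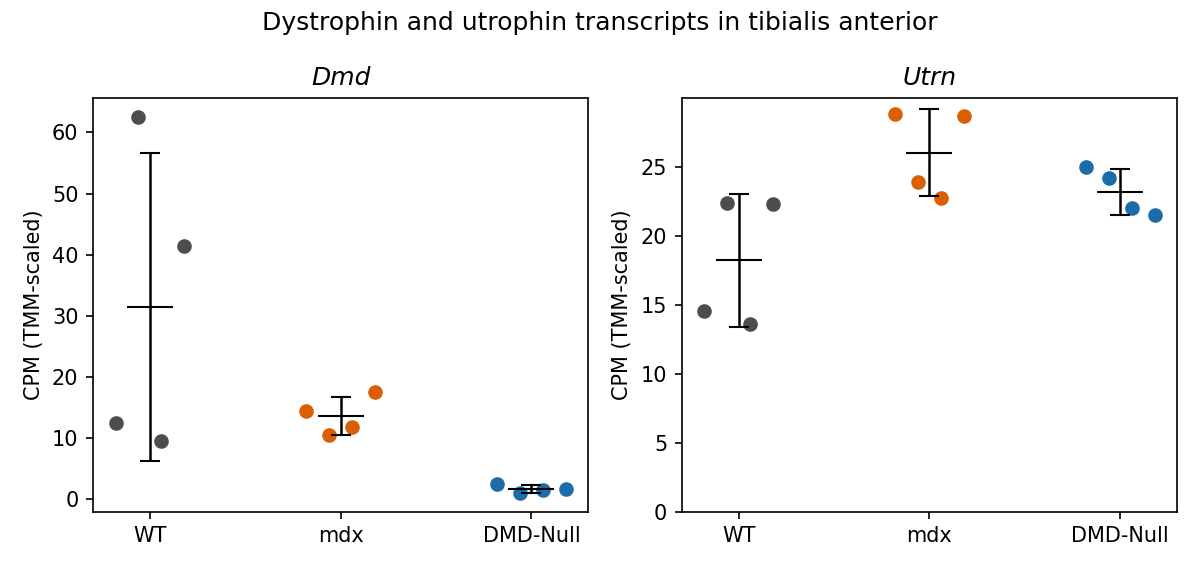
CPM of Dmd and Utrn (y axes) in each library (points) of WT, mdx and DMD-Null (x axes), with the mean and SD of each group. Dmd averages 1.68 in DMD-Null against 13.6 in mdx and 31.5 in WT, and Utrn averages 23.2, 26.0 and 18.2.

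The comparison of mdx with WT asks how muscle of the established model differs from healthy muscle at this age. Transcripts typical of liver and lung also differed between these libraries, so the comparison does not tell genotype from other differences between the groups. In mdx muscle, genes of regenerating and embryonic fibres, of the extracellular matrix and of macrophages rose, and genes of fatty acid oxidation fell. Genes of mitochondrial respiration also fell, a list call that ended with an estimated correlation (camera adjusted p = 0.314). Mymk (ENSMUSG00000009214, chromosome 2 from 27061636 to 27072179), which encodes the myoblast fusion protein myomaker, rose from 0.325 ± 0.324 to 30.05 ± 5.88 CPM (SD, n = 4), a log2 fold change of 6.59 (SE 0.70, edgeR adjusted p = 8.42e-05). Its partner in fusion, Mymx, rose by 5.27. Of the 24 regeneration genes tested, 19 rose, 4 fell and 1 did not pass, with the same numbers adjusted over the list alone. Embryonic myosin Myh3 rose by 3.43 and the differentiation factor Myog by 4.19. Those that fell were Csrp3 (-2.02), Nrap (-1.71), Myh8 (-1.36) and Xirp1 (-1.21), of which Csrp3, Nrap and Xirp1 belong to the contractile and junctional apparatus of the fibre and Myh8 is perinatal myosin. The list as a whole rose (camera adjusted p = 7.15e-17).

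Satellite cells, the stem cells of muscle, were represented by 14 tested genes, of which 6 rose, 2 fell and 6 did not pass, again with the same numbers adjusted over the list alone. Peg3 (ENSMUSG00000002265, chromosome 7 from 6703892 to 6730421), an imprinted gene of stem and progenitor cells, rose from 14.7 ± 4.51 to 87.3 ± 16.2 CPM (SD, n = 4), and the chemokine receptor Cxcr4 rose by 2.53. Vcam1, an adhesion molecule also found on endothelium, rose by 1.55, while Cdh15, the cadherin of satellite cells, fell by 0.88. Neither this fall nor that of the receptor gene Notch3 passed with GC-corrected offsets (edgeR adjusted p = 0.0686 and 0.724) or without WT 1 and WT 3 (edgeR adjusted p = 0.333 and 0.146). The list rose (camera adjusted p = 0.00905), but not with an estimated correlation (adjusted p = 0.079). Pax7, the defining factor of these cells, was under the filter, with 145 to 278 counts in mdx and 98 to 203 in WT.

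Of 28 matrix genes, 24 rose and none fell (25 rose adjusted over the list alone). The metalloproteinase inhibitor Timp1 (ENSMUSG00000001131, chromosome X from 20870166 to 20874735) rose by 4.43 (SE 0.38, edgeR adjusted p = 2.82e-05) and the matricellular protein Postn from 9.65 ± 1.102 to 102 ± 24.8 CPM (SD, n = 4). The matrix list had a camera adjusted p of 1.06e-20. Macrophage genes moved still more evenly, with 27 of 28 up and 1 not past, the same adjusted over the list alone (camera adjusted p = 7.47e-33). The monocyte chemokine receptor Ccr2 rose by 4.07 and the integrin Itgax by 3.81. Of 15 genes of fibro-adipogenic progenitors, 9 rose, led by Pdgfra (1.94), and 1 fell, also adjusted over the list alone (camera adjusted p = 2.26e-05, 0.197 with an estimated correlation). Of 13 genes of antigen presentation, 8 rose and none fell, also over the list alone, with the class II gene H2-Aa at 14.3 ± 4.67 CPM in WT and 133 ± 7.90 in mdx (SD, n = 4; camera adjusted p = 1.1e-05, adjusted p = 0.241 with an estimated correlation).

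Complement genes rose in 12 of 16 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 1.49e-05, adjusted p = 0.197 with an estimated correlation), and C5ar1, a complement receptor of myeloid cells, rose by 2.85. The cytokine list had 7 of 12 members up (8 adjusted over the list alone), among them the monocyte attractant Ccl7 at 2.66 (camera adjusted p = 0.00782, adjusted p = 0.198 with an estimated correlation). Of 7 granulocyte genes 3 rose, also over the list alone, including Retnlg at 2.90 (camera adjusted p = 0.0379, adjusted p = 0.359 with an estimated correlation and 0.0521 with GC-corrected offsets). Of 18 interferon genes, 2 rose and 0 adjusted over the list alone, and the list test did not pass (camera adjusted p = 0.215). It did pass without WT 1 and WT 3 (camera adjusted p = 0.0398). Of 15 senescence and p53 genes, 9 rose and 1 fell, also over the list alone (camera adjusted p = 0.000855). They were led by Cdkn2a (ENSMUSG00000044303, chromosome 4 from 89274471 to 89294653), a cell cycle inhibitor, at 0.447 ± 0.137 CPM in WT and 13.4 ± 4.16 in mdx (SD, n = 4). Of 14 cell cycle genes 8 rose and 1 fell, also over the list alone (camera adjusted p = 0.00378, adjusted p = 0.201 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 2.99.

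The neuromuscular junction and denervation list had 7 of 18 genes up and 1 down (8 and 2 adjusted over the list alone), led by Chrng, the embryonic acetylcholine receptor subunit, at 5.06 (camera adjusted p = 1.1e-05, adjusted p = 0.106 with an estimated correlation). Of 18 genes of the dystrophin complex, 6 rose and 2 fell, also adjusted over the list alone, and the list test did not pass (camera adjusted p = 0.215). Syntrophin gene Sntb1 rose by 1.80 and Nos1, the nitric oxide synthase of the sarcolemma, fell from 224 ± 67.1 to 85.7 ± 12.1 CPM (SD, n = 4). Tendon genes rose in 3 of 10 cases, also over the list alone, without a list call (camera adjusted p = 0.112), though the list was called with GC-corrected offsets (camera adjusted p = 0.0225). Erythroid genes rose in 1 and fell in 1 of 8 cases, also over the list alone (camera adjusted p = 0.259).

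Of 75 genes of oxidative phosphorylation, 59 fell and none rose (63 adjusted over the list alone). Subunits of ATP synthase led, with Atp5e at -1.65 and Atp5k at -1.63. The list fell (camera adjusted p = 2.49e-11), but not with an estimated correlation (adjusted p = 0.314), and without WT 1 and WT 3 36 of its genes fell, with a median of -0.38 in place of -0.77. Of 22 genes of fatty acid oxidation 15 fell and none rose, also over the list alone (camera adjusted p = 1.47e-09). Fabp3, the fatty acid binding protein of muscle, fell from 519 ± 126 to 118 ± 8.09 CPM (SD, n = 4). In glycolysis, 10 of 20 genes fell and 1 rose (11 and 2 adjusted over the list alone), with the gluconeogenic enzyme Fbp2 at -2.44 (camera adjusted p = 0.00398, adjusted p = 0.327 with an estimated correlation). Adipocyte genes fell in 6 of 10 cases and rose in none (7 and 1 adjusted over the list alone), with the lipid droplet gene Cidec at -2.22 (camera adjusted p = 0.00321, adjusted p = 0.163 with an estimated correlation).

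Of 19 fast-fibre genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone). Fast myosin Myh1 fell by 1.63 and the muscle phosphoglycerate mutase Pgam2 by 1.46, whereas Mybph rose by 1.41. The list fell (camera adjusted p = 0.00782), but not with an estimated correlation (adjusted p = 0.581), and without WT 1 and WT 3 its camera adjusted p was 0.671 with a median of -0.27 in place of -0.95. Slow-fibre genes had 4 of 15 members up and 5 down (5 and 7 adjusted over the list alone) and no list call (camera adjusted p = 0.357). Myl3 (ENSMUSG00000059741, chromosome 9 from 110741861 to 110769798), a slow-fibre myosin light chain, fell from 143 ± 124 to 5.87 ± 2.22 CPM (SD, n = 4), and Myh2, the myosin of oxidative fast fibres that stands in this list, fell by 3.16. Without WT 1 and WT 3, which held the most Myh2, the changes of Myl3 and Myh2 were -2.98 and -1.87, and the slow-fibre median was 0.27 in place of -0.31, also without a list call (camera adjusted p = 0.332). The ribosomal protein genes fell in 19 and rose in 1 of 46 cases (27 and 1 adjusted over the list alone), among them Rplp2 at -1.10 (camera adjusted p = 0.000267, adjusted p = 0.579 with an estimated correlation). Without WT 1 and WT 3 the camera adjusted p was 0.176. Endothelial genes fell in 7 of 15, smooth muscle and pericyte genes in 6 of 12, and Schwann cell genes in 4 of 8 cases with 1 up. Adjusted over the list alone, these falls numbered 7, 7 and 5. They were led by Vwf (-1.73), Myh11 (-1.61) and Prx (-1.68), and the camera adjusted p were 0.0356, 0.0248 and 0.0379. These 3 calls ended with an estimated correlation (adjusted p = 0.229, 0.314 and 0.314) and without WT 1 and WT 3 (adjusted p = 0.0624, 0.0927 and 0.183), and those of smooth muscle and Schwann cell genes also with GC-corrected offsets (adjusted p = 0.0763 each).

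Among genes with a mean FPKM of at least 5 in a group and no overlap between groups, Mymk, Scgb1a1, Gm48395, Cdkn2a and C1qtnf3 had the largest rises and BC048679, Ppp1r1a, Myl3, Mup7 and 1700001O22Rik the largest falls. Ppp1r1a (ENSMUSG00000022490, chromosome 15 from 103530279 to 103538003), an inhibitor of protein phosphatase 1, fell from 65.8 ± 28.2 to 2.05 ± 0.254 CPM (SD, n = 4; edgeR adjusted p = 4.30e-06). BC048679 (ENSMUSG00000061877, chromosome 7 from 81494275 to 81498281) fell by 6.94 on the log2 scale. Mup7, a major urinary protein gene of liver, fell by 4.43, and genes typical of liver fell with it, with sums over 52 of them of 1164 to 1283 CPM in WT, unscaled by TMM, and 174 to 322 in mdx. Scgb1a1, which encodes the secretoglobin of airway club cells, rose by 5.69, and sums over 15 lung genes were 24.4 to 28.9 CPM in mdx and 5.90 to 7.66 in WT.

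In all, 4001 of 11376 genes differed between mdx and WT, 1709 higher and 2292 lower, of which 872 and 920 changed at least 2-fold. The 4 mdx libraries did not overlap with the 4 WT libraries in 3494 genes, where chance gives 2.86%. Genes that fell had a median GC content of 54.2% and those that rose 48.6%, the direction of the trend of WT 1 and WT 3. With GC-corrected offsets, 3306 of the calls kept their direction and 0 reversed. The call count without WT 1 and WT 3 was 2649, of which 1943 were shared. Without WT 1 and WT 3 the members past the threshold also changed by more than 1.5 times in other lists, counting those with at least 3 in either fit. The genes that fell were 0 for 11 in the fast-fibre list, 0 for 19 in ribosomal proteins, 3 for 10 in glycolysis, 1 for 7 in endothelium, 3 for 6 in smooth muscle, 1 for 4 in Schwann cells, 3 for 7 in calcium handling, 2 for 4 in regeneration and 0 for 3 in the Notch pathway. Those that rose were 4 for 9 in senescence, 2 for 6 in the dystrophin complex, 2 for 5 in the Notch pathway and 5 for 9 in the unfolded protein response. More were called in denervation (11 up for 7), calcium handling (4 up for 1) and atrophy (4 down for 0). The call count was 6874 without WT 2, 2342 without WT 3, and 2355, 2447 and 2300 without mdx 1, mdx 3 and mdx 4. The split depended on scaling. With library totals alone 3350 genes were higher and 707 lower at a median shift of 0.42 on the log2 scale, and with limma on log2(FPKM + 1) 5049 were higher and 672 lower (shift 0.35), or 5373 and 538 on TPM (shift 0.43). Under library totals the medians of the slow-fibre, ribosomal protein and calcium handling lists were above 0, at 0.11, 0.01 and 0.19, as were those of the polarity (0.29) and atrophy (0.39) lists, and the granulocyte call ended (adjusted p = 0.114).

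DMD-Null was compared with WT in the same way. Genes of regenerating fibres and of the matrix rose, and genes of fat oxidation fell. Macrophage genes rose and genes of respiration fell as well, list calls that ended with an estimated correlation (camera adjusted p = 0.0668 and 0.268). Mymk rose to 20.1 ± 7.53 CPM (SD, n = 4), a log2 fold change of 6.02 (SE 0.69, edgeR adjusted p = 0.000143), and Mymx by 4.45. Of the 24 regeneration genes 19 rose and 3 fell (19 and 4 adjusted over the list alone), with Myog at 3.84 and Myh3 at 2.91 among the former and Myh8 (-1.55), Nrap (-1.51) and Csrp3 (-1.46) the latter (camera adjusted p = 1.83e-15). Timp1 rose to 26.7 ± 7.37 CPM from 0.883 ± 0.145 (SD, n = 4) and the fibrillar collagen Col3a1 by 3.29, within a matrix list that had 24 of 28 genes up and none down (26 up adjusted over the list alone, camera adjusted p = 8.28e-24). Of 28 macrophage genes, 26 rose and none fell (28 up adjusted over the list alone), with Ccr2 at 3.90 and Itgax at 3.65 (camera adjusted p = 3.85e-30, adjusted p = 0.0668 with an estimated correlation).

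Of the 14 satellite cell genes, 6 rose and none fell (6 and 2 adjusted over the list alone). Peg3 rose to 96.4 ± 18.95 CPM (SD, n = 4) and Cxcr4 by 1.96, and Vcam1, the transcription factor Msc and the growth factor signalling genes Spry1 and Fgfr1 were the other 4. The list rose (camera adjusted p = 0.0129), but not with an estimated correlation (adjusted p = 0.0997). Pax7 had 168 to 274 counts in DMD-Null. Of 15 genes of fibro-adipogenic progenitors 9 rose, also over the list alone, led by Mfap5 (1.85, camera adjusted p = 4.66e-06, adjusted p = 0.16 with an estimated correlation). The dystrophin complex list had 4 of 18 genes up and 2 down, also over the list alone, with Sntb1 (1.75) and Sntb2 (1.04) up and no list call (camera adjusted p = 0.115). The junction and denervation list had 7 of 18 up and 1 down (8 and 3 adjusted over the list alone), with Chrng at 4.45 (camera adjusted p = 1.86e-05, adjusted p = 0.137 with an estimated correlation).

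Among genes of inflammation, 12 of 16 complement genes rose and 2 fell (13 and 2 adjusted over the list alone), and 6 of 12 cytokine genes rose, also over the list alone. C5ar1 rose by 3.09, and so did Ccl7. Both lists rose (camera adjusted p = 2.09e-05 and 0.00532, adjusted p = 0.173 each with an estimated correlation). Antigen presentation genes rose in 5 of 13 cases, also over the list alone, with H2-Aa at 82.0 ± 28.1 CPM (SD, n = 4; camera adjusted p = 0.000826, adjusted p = 0.318 with an estimated correlation). Of 7 granulocyte genes 2 rose (3 adjusted over the list alone) and of 18 interferon genes 1 rose (0 adjusted over the list alone), without list calls (camera adjusted p = 0.0981 and 0.145). These lists were called without WT 1 and WT 3 (camera adjusted p = 0.0293 and 0.0243). Senescence and p53 genes rose in 6 of 15 cases and fell in 1 (8 and 1 adjusted over the list alone), with Cdkn2a at 4.65 (camera adjusted p = 0.000676). Cell cycle genes rose in 7 of 14 cases (8 up and 3 down adjusted over the list alone), with Rrm2 at 2.84 (camera adjusted p = 0.00198, adjusted p = 0.173 with an estimated correlation). Tendon genes rose in 3 of 10 cases, also over the list alone, with the matrix protein Tnc at 2.45 (camera adjusted p = 0.0145, adjusted p = 0.318 with an estimated correlation). Of 8 erythroid genes, 6 fell and 1, the platelet factor Pf4, rose, also over the list alone. The hemoglobin gene Hba-a2 fell by 1.91 from 229 ± 90.2 to 61.2 ± 17.2 CPM (SD, n = 4). The list fell (camera adjusted p = 0.0127, adjusted p = 0.339 with an estimated correlation), a call that ended without WT 1 and WT 3 (adjusted p = 0.067).

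Of 75 genes of oxidative phosphorylation 55 fell and none rose (61 adjusted over the list alone), led by Atp5k (-1.55) and Uqcrc1 (-1.47), a subunit of complex III (camera adjusted p = 3.19e-12, adjusted p = 0.268 with an estimated correlation). Without WT 1 and WT 3, 31 of them fell, with a median of -0.36 in place of -0.72. Fatty acid oxidation genes fell in 15 of 22 cases (16 adjusted over the list alone), with Fabp3 at 97.0 ± 17.3 CPM (SD, n = 4; camera adjusted p = 9.32e-12). Of 20 glycolytic genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Fbp2 at -1.71 (camera adjusted p = 0.0145, adjusted p = 0.378 with an estimated correlation, 0.182 without WT 1 and WT 3). Adipocyte genes fell in 3 and rose in 1 of 10 cases (5 and 1 adjusted over the list alone), with the triglyceride synthesis gene Dgat2 at -2.22 (camera adjusted p = 0.00413, adjusted p = 0.16 with an estimated correlation). Fast-fibre genes fell in 11 and rose in 1 of 19 cases (13 and 1 adjusted over the list alone), with Myh1 at -1.56 and Mybph at 1.86 (camera adjusted p = 0.00374, adjusted p = 0.505 with an estimated correlation, 0.572 without WT 1 and WT 3). Slow-fibre genes rose in 3 and fell in 5 of 15 cases (4 and 5 adjusted over the list alone), with Myl3 at -3.64 and Myh2 at -2.54 and no list call (camera adjusted p = 0.51). Without WT 1 and WT 3 these were -2.01 and -1.24, the latter no longer past the threshold (edgeR adjusted p = 0.0793), and the slow-fibre median was 0.66 in place of -0.16 (camera adjusted p = 0.182).

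Ribosomal protein genes fell in 8 and rose in 1 of 46 cases (0 and 0 adjusted over the list alone), with Rplp2 at -1.06 (camera adjusted p = 0.00198, adjusted p = 0.59 with an estimated correlation, 0.713 without WT 1 and WT 3). Endothelial genes fell in 6 of 15 cases, led by Egfl7 (-1.66), smooth muscle and pericyte genes in 5 of 12, led by Myh11 (-1.46), and Schwann cell genes in 3 of 8 with 1 up, led by Prx (-1.42). Adjusted over the list alone, the falls numbered 8, 5 and 5. The camera adjusted p were 0.0145, 0.0145 and 0.0424, and with an estimated correlation the adjusted p were 0.173, 0.268 and 0.308. The smooth muscle and Schwann cell calls also ended without WT 1 and WT 3 (adjusted p = 0.0714 and 0.233) and with GC-corrected offsets (adjusted p = 0.0541 and 0.0977).

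Among genes with a mean FPKM of at least 5 in a group and no overlap between groups, Mymk, Timp1, Gm48395, Cdkn2a and the stress-responsive Ankrd1 had the largest rises, and BC048679, 1700001O22Rik, 0610040J01Rik, Ppp1r1a and Dusp26 the largest falls. Ppp1r1a stood at 2.96 ± 0.660 CPM and Ankrd1 at 177 ± 76.6, against 12.2 ± 8.87 in WT (SD, n = 4). Liver genes also fell, with sums of 394, 64.2, 311 and 306 CPM in DMD-Null 1 to 4. In all, 3241 genes differed, 1471 higher and 1770 lower, 753 and 752 of them at least 2-fold. The groups did not overlap in 2477 genes, where chance gives 2.86%. Genes that fell had a median GC content of 54.0% and those that rose 48.9%. With GC-corrected offsets, 2835 calls kept their direction and 0 reversed, and 1708 were shared without WT 1 and WT 3. Counted as for mdx, the genes that fell were then 1 for 11 in the fast-fibre list, 0 for 8 in ribosomal proteins, 2 for 7 in glycolysis, 2 for 6 in endothelium, 0 for 3 in Schwann cells, 2 for 6 in the erythroid list, 3 for 5 in the slow-fibre list and 1 for 3 in regeneration, and those that rose were 2 for 4 in the Notch pathway. More rose in antigen presentation (12 for 5) and the slow-fibre (6 for 3), granulocyte (4 for 2) and interferon lists (4 for 1). The call count was 6404 without WT 2, 1936 without WT 3, and 2102, 1707 and 1709 without DMD-Null 1, 2 and 3. With library totals alone 3360 genes were higher and 574 lower (median shift 0.44), with limma on log2(FPKM + 1) 4962 and 565 (shift 0.36) and on TPM 5613 and 432 (shift 0.46). Under library totals the medians of the slow-fibre, calcium handling, ribosomal protein and glycolysis lists were above 0, at 0.26, 0.14, 0.11 and 0.02, as were those of the polarity (0.26) and atrophy (0.37) lists, and the tendon and ribosomal protein calls ended (adjusted p = 0.051 and 0.0975).

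**Figure D3:**
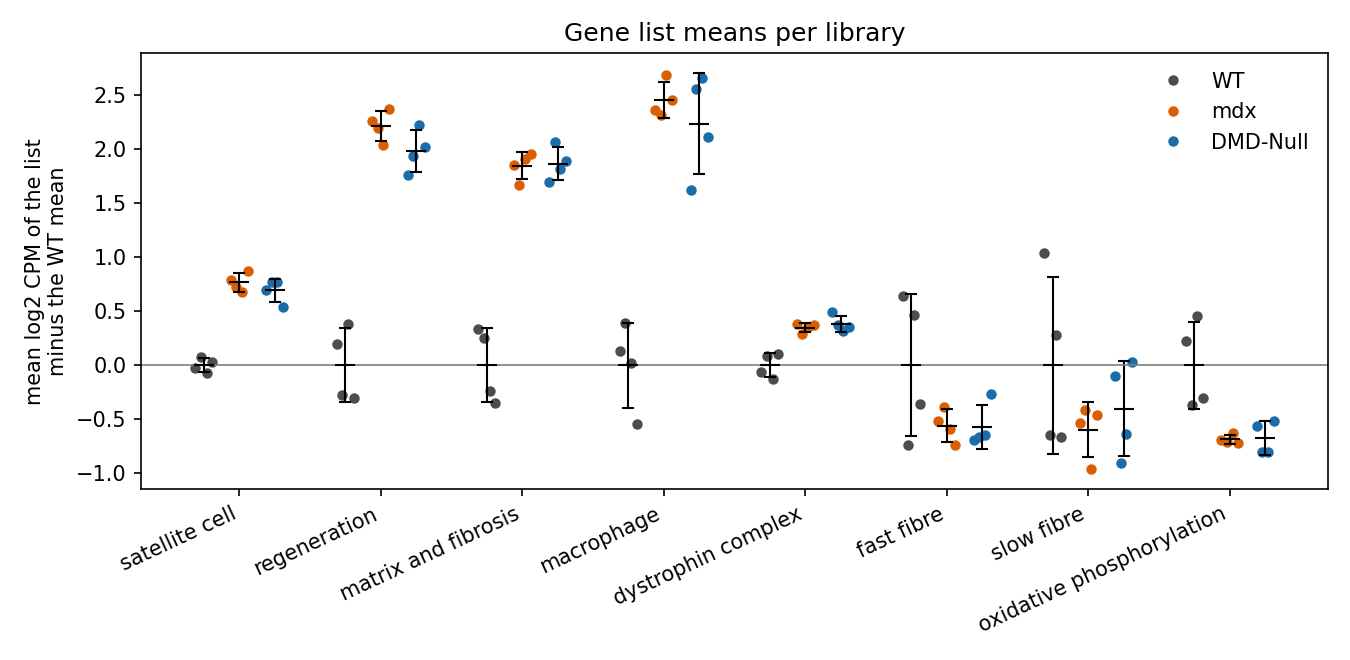
Mean log2 CPM over the tested genes of the 8 lead lists, relative to the WT mean (y axes), in each library of WT, mdx and DMD-Null (x axes), with the group mean and SD. The regeneration, matrix and macrophage means lie 2.22, 1.85 and 2.46 above WT in mdx and 1.99, 1.87 and 2.24 above WT in DMD-Null.

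Means over the lead lists gave a value per library. The regeneration mean was 3.94 ± 0.34 in WT, 6.16 ± 0.14 in mdx and 5.93 ± 0.19 in DMD-Null (log2 CPM; SD, n = 4), and the satellite cell mean was 3.12 ± 0.06, 3.88 ± 0.08 and 3.81 ± 0.11. The dystrophin complex, satellite cell, regeneration, matrix, macrophage and oxidative phosphorylation means each differed from WT in both mutants, at the smallest exact permutation p of 0.0286 (adjusted p = 0.0381). The fast-fibre means (mdx -0.56, exact permutation adjusted p = 0.196, and DMD-Null -0.57, adjusted p = 0.294) and slow-fibre means (mdx -0.60, adjusted p = 0.286, and DMD-Null -0.40, adjusted p = 0.457) did not. Between DMD-Null and mdx none of the 8 means differed, the regeneration mean by -0.23 (exact permutation p = 0.114, adjusted p = 0.869) and the satellite cell mean by -0.07 (exact permutation p = 0.343, adjusted p = 0.869).

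The mutants' responses were compared across genes, which are not independent replicates. Of the genes past the threshold in both comparisons with WT, 1357 were up in both, including Mymk, Cdkn2a and Postn, 1624 were down in both, including Ppp1r1a, Myl3 and Fabp3, and 1, Sftpc, went opposite ways. The fall of Sftpc in DMD-Null rests on 17 counts in all of WT against 0 in DMD-Null. Independent lists of these sizes would share 221 and 357, which takes no account of the WT libraries common to both comparisons. Over all tested genes 94.5% had changes of the same sign, against 66.7% in the simulation with shared WT libraries. The differences between group means of log2 CPM correlated with r = 0.964 (edgeR's log2 fold changes with 0.956). In 100 simulations of unchanged groups sharing simulated WT libraries, r had a mean of 0.504 and a maximum of 0.541. These simulations lack the split of WT 1 and WT 3 from the other WT libraries. The covariance of the log2 CPM differences was 0.745 against a simulated 0.0516, a difference of 0.694. With 2 WT libraries given to each mutant, r was 0.885 to 0.914 where WT 1 and WT 3 were parted. It was 0.511 where they went with mdx and 0.576 where they went with DMD-Null. The slope of the DMD-Null changes on those of mdx was 0.938.

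**Figure D4:**
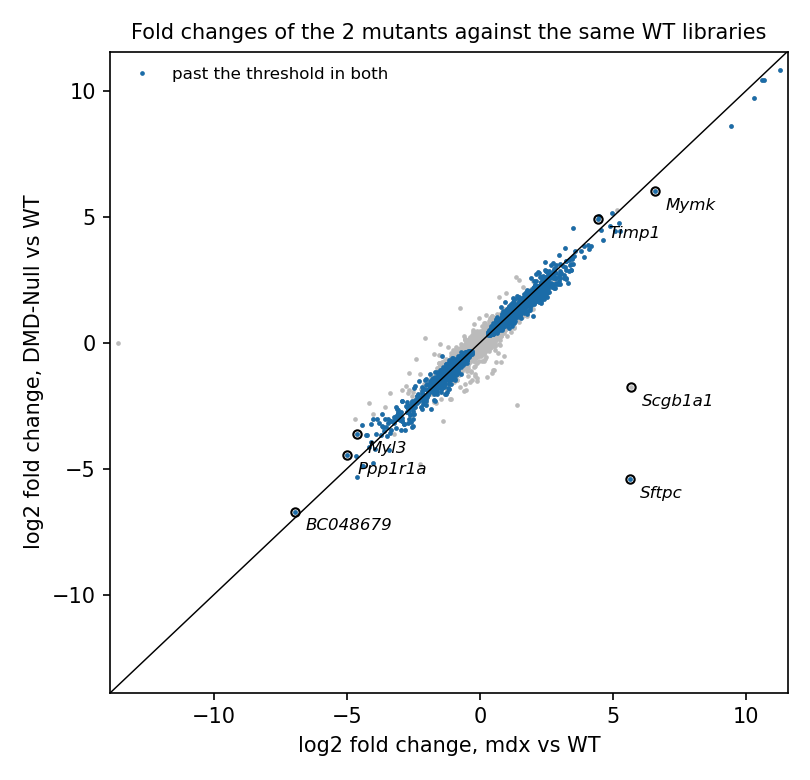
Log2 fold change of each tested gene in mdx against WT (x axis) and DMD-Null against WT (y axis), with genes past the threshold in both comparisons in blue and a line at equal change. The points, edgeR's estimates, follow the line (r = 0.956), Mymk lies at 6.59 and 6.02 and Ppp1r1a at -5.00 and -4.47, and Scgb1a1 and Sftpc lie off it.

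The comparison of DMD-Null with mdx asks whether muscle of these mutants differs, and the series title names regeneration and satellite cell function as points of interest. Satellite cell genes did not differ as a list (median 0.00, camera adjusted p = 0.448), and 0 of its 14 members passed. Peg3 differed by 0.14 (SE 0.22, edgeR adjusted p = 1) and Pax7 by 0.20. Of the 24 regeneration genes none passed, with Mymk at -0.58 (SE 0.52, edgeR adjusted p = 1), but the list as a whole was lower in DMD-Null, by a median of -0.28 (camera adjusted p = 2.78e-05, adjusted p = 0.585 with an estimated correlation). The macrophage list was lower by a median of -0.17 (camera adjusted p = 8.52e-07, adjusted p = 0.832 with an estimated correlation). Antigen presentation genes were lower by -0.19 (camera adjusted p = 1.18e-07, adjusted p = 0.585 with an estimated correlation), with H2-Aa at -0.69 (edgeR adjusted p = 1).

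Erythroid genes had the largest list median, -1.11 (camera adjusted p = 1.75e-07, adjusted p = 0.585 with an estimated correlation), and 4 of the 8 were lower adjusted over the list alone. The hemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt differed by -1.34, -1.32, -1.17 and -1.16 (edgeR adjusted p = 1 each). Tendon genes were higher by a median of 0.35 (camera adjusted p = 0.00414, adjusted p = 0.832 with an estimated correlation), glycolytic genes by 0.10 (camera adjusted p = 0.0113, adjusted p = 0.832 with an estimated correlation) and ribosomal protein genes by 0.09 (camera adjusted p = 0.0101, adjusted p = 0.864 with an estimated correlation). Apart from the 4 erythroid genes, no member of any of the 31 lists passed in edgeR, over all genes or adjusted over the list alone. With an estimated correlation 0 lists were called and with fry also 0, where camera called 7. The remaining 24 lists were not called, among them the matrix (median 0.08, camera adjusted p = 0.659), oxidative phosphorylation (0.02, 0.768), fast-fibre (-0.01, 0.768), slow-fibre (0.15, 0.23) and dystrophin complex lists (0.01, 0.659).

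Between DMD-Null and mdx, 120 of 11376 genes had an unadjusted edgeR p under 0.05 (354 with the 8 libraries alone). Both are smaller shares than the 0.05 that chance gives. Only 2 genes passed in edgeR, both lower in DMD-Null, while DESeq2 called 6 and limma on log2(FPKM + 1) called 2. The 2 genes that passed in edgeR encode proteins of the lung epithelium. Sftpc (ENSMUSG00000022097, chromosome 14 from 70520949 to 70524081), surfactant protein C, had 258 to 348 counts in the mdx libraries, 0 in DMD-Null and 17 in all of WT. The mdx level of 4.15 ± 0.429 CPM (SD, n = 4) was at least 382-fold higher than in DMD-Null, taking 3 counts over the group (edgeR adjusted p = 0.0024). Scgb1a1 (ENSMUSG00000024653, chromosome 19 from 9083636 to 9087958) had 289 to 471 counts in mdx, 8 in all of DMD-Null and 21 in all of WT, with a log2 fold change of -7.46 (SE 0.89, edgeR adjusted p = 0.0129). Its call ended without mdx 3, mdx 4, DMD-Null 1, DMD-Null 2 or DMD-Null 4, which left 1 gene each time. Capn3 (ENSMUSG00000079110, chromosome 2 from 120463572 to 120504918), a muscle protease, was 0.88 higher in DMD-Null (SE 0.13, edgeR adjusted p = 0.0974) and passed with GC-corrected offsets (0.87, edgeR adjusted p = 0.0195). It also passed with the 8 libraries alone (0.87, edgeR adjusted p = 0.0309). DESeq2 added Capn3, Gm20716, mt-Tg and Peak1 to the 2 genes. Of these, Gm20716 (DESeq2 log2 fold change 27.3) and Peak1 (-1.42) were called in no other fit. The groups did not overlap in 255 of 11376 genes, a smaller share than the 2.86% that chance gives.

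Genes near Dmd were examined for an effect of the locus. Of 54 tested genes within 10 Mb of Dmd, 20 differed in mdx and 16 in DMD-Null against WT, or 37.0% and 29.6%, against 35.2% and 28.5% of genes elsewhere (Fisher's exact test p = 0.776 and 0.880). Over the whole X chromosome, 108 and 79 of 336 tested genes differed (Fisher's exact test adjusted p = 0.542 and 0.235), and no chromosome passed this test, with lowest adjusted p of 0.107 in mdx and 0.0593 in DMD-Null. Between DMD-Null and mdx 0 of the 54 passed in edgeR, nor did any of 100 tested genes within 20 Mb.

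**Figure D5:**
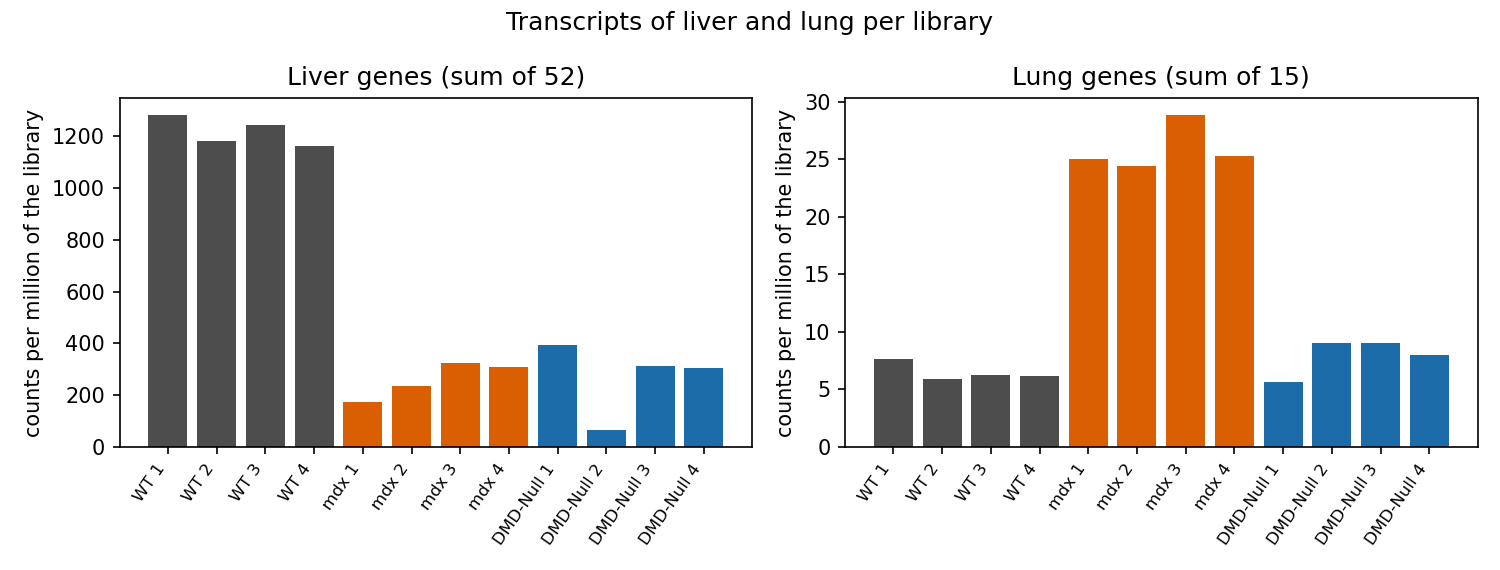
Sums over the genes of the liver list (52) and of the lung list (15), in CPM without TMM factors (y axes), in each of the 12 libraries (bars). Liver sums are 1164 to 1283 in WT, 174 to 322 in mdx and 64.2 to 394 in DMD-Null, and lung sums are 24.4 to 28.9 in mdx and 5.63 to 9.05 elsewhere.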

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

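The tests of the GC trend as the whole of the difference between WT libraries and of genotype alone for liver genes were chosen only after the result was seen, the latter in place of the ratio among DMD-Null libraries, which turned out to rest on DMD-Null 2. Of 222 groups of 4 libraries examined for a single library far from the other 3, 14 were marked, where chance gives about 1 in 20, or 11.1. The ratio given for each is the gap to the nearest library over the range of the group.

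In DMD-Null, DMD-Null 4 had the high GC correlation of 0.449 against -0.579 to -0.426 (ratio 0.851). It was also apart in the fast-fibre mean (12.46 against 12.03 to 12.07 log2 CPM, ratio 0.901), in the sarcoplasmic calcium pump Atp2a1 (37990 against 25261 to 26086 CPM, ratio 0.935) and in Sntb1 (3.42 against 9.42 to 10.2 CPM, ratio 0.885). DMD-Null 3 alone held reads of Scgb1a1 (0.109 CPM against 0, ratio 1). In WT, BC048679 was high in WT 3 (39.3 against 7.76 to 10.99 CPM, ratio 0.898), Mybph in WT 1 (71.9 against 23.2 to 28.9, ratio 0.884) and C1qtnf3 in WT 2 (1.13 against 0.484 to 0.582, ratio 0.849). In mdx, Mymx was high in mdx 4 (7.26 against 3.85 to 4.29 CPM, ratio 0.871) and Cdkn2a in mdx 2 (19.5 against 10.9 to 11.99, ratio 0.869). In mdx 3, Ccr2 (18.4 against 14.4 to 14.97 CPM, ratio 0.859) and Ankrd1 (294 against 138 to 164, ratio 0.837) were high. Ddit3 (9.34 against 11.6 to 11.99, ratio 0.852) and Nrap (1033 against 1113 to 1128, ratio 0.841) were low there.

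WT 1 and WT 3 stood apart from WT 2 and WT 4, and no label parts these libraries, so no biological explanation was tested. On the first principal component the gap between the pairs was 2.80 times the larger distance within a pair, and 2.01 times after GC correction, which argues against the GC trend as the whole of it. A curve on GC content removed 34.3% of the mean absolute log ratio between the pairs. Loss of long transcripts may contribute and cannot be told apart from its absence, because the rank correlation with transcript length given GC content, -0.150, lay between the bounds set for either. The step that produced the trend is not known.

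Liver transcripts were high in the WT libraries and lung transcripts in the mdx libraries. Without TMM factors, albumin (Alb) stood at 395 to 428 CPM in WT and 36.5 to 79.0 in mdx. In DMD-Null 1 to 4 it stood at 107, 0.132, 70.1 and 78.4. Scaled by TMM factors, Alb was 622 CPM in WT 1 and 428 in WT 2. Among the DMD-Null libraries the highest level exceeded the lowest by a median of 49.2 times over the 52 liver genes, but by 1.31 times without DMD-Null 2. Over 48 of these, left after removing 4 that were not at least 10 times lower in DMD-Null 2 than in WT, the log2 ratio of WT 1 and WT 3 to WT 2 and WT 4 had a slope of 0.0263 (SE 0.0368) per 10 percentage points of GC, and 0.0126 (SE 0.0371) over all 52, against 1.12 (SE 0.0111) over 11322 other genes. If a technical step gave WT 1 and WT 3 their GC trend, this argues against liver RNA present before that step. It then also argues against an effect of genotype alone, since transcripts made in the muscle would carry the trend. A technical source was not established, and if the trend lies in muscle expression the slopes cannot decide either question. Liver reads of other libraries assigned to WT at sequencing remain a candidate explanation. For lung reads so assigned to mdx, the ratios of the 5 lung genes over 10 times lower in DMD-Null differed between the 4 mdx libraries by more than counting error (chi-square p = 1.82e-11), as did the liver genes between the WT libraries (chi-square p = 6.93e-62). This test covers counting error only, so lung reads of other libraries and lung RNA in the samples may each be the source.

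The other organ lists gave little. Of 8 heart genes 3 were tested, Myl4, Actc1 and Sln, all members of the fixed lists and up in both mutants against WT. Of 8 brain genes 7 were tested, 2 of them shared with fixed lists (Mbp and Camk2a), and 2 fell in mdx and 1 in DMD-Null against WT. Of 7 intestine genes 1 was tested and did not pass, and 0 of the pancreas (12), kidney (8) and testis (6) genes were tested, with sums of at most 5.85, 0.633 and 0.175 CPM. Of 15 lung genes 4 were tested, with 3 up and 1 down in mdx and 1 up and 2 down in DMD-Null against WT, and 2 lower in DMD-Null than in mdx. Of 52 liver genes 46 were tested, and 41 fell in mdx, 40 in DMD-Null and 0 between the mutants in edgeR.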

How the results depend on the processing

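GC correction, the fits without WT 1 and WT 3, without these and DMD-Null 4, on library totals, of Dmd and the lists in 8 libraries, and of Dmd without single replicates were chosen only after the data were seen. In the fits where this was checked, no named value changed its direction past the threshold, and no list changed camera's direction. The counts and their split by direction moved. Fits without such a check included DESeq2, TPM, quantile normalization and array weights. For named genes other than Dmd they also included library totals and the 8 libraries. Under library totals the ribosomal protein list in mdx stayed down (camera adjusted p = 0.0166) at a median of 0.01. So did the glycolysis list in DMD-Null (camera adjusted p = 0.0238, median 0.02). Of named genes 1535 values were the same, 100 lost and 3 gained the call, and of gene lists 1889, 118 and 39.

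Counts of mdx against WT (4001) moved to 1701 at a mean FPKM of at least 5, 1792 at 2-fold, 1466 at an adjusted p of 0.01, 2649 without WT 1 and WT 3, 2268 with 8 libraries and 9193 with array weights, where 91 shared calls had the other sign. Without single replicates they were 2300 to 6874. Counts of DMD-Null against WT (3241) moved to 1483, 1505, 1207, 1398 with 8 libraries and 9121 with array weights, where 93 shared calls had the other sign, and to 5527, 5430 and 5486 with limma on log2(FPKM + 1), 0.1 and 0.5, and 6045 on TPM, with 1707 to 6404 without single replicates. Counts of DMD-Null against mdx (2) were 1 at a mean FPKM of at least 5, 1 at an adjusted p of 0.01, and 1 without WT 1, WT 3 and DMD-Null 4. At that mean FPKM the 1 gene was Capn3, newly called, since Sftpc and Scgb1a1 lay under that filter. The counts were 4 with 8 libraries, with or without GC correction, 4 with array weights, 6 with DESeq2 and 1 to 2 without single replicates. Stricter filters and thresholds pass fewer genes by construction. For the others the cause was not tested.

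With a replicate block the counts were 2377, 1869 and 0 (92 at an unadjusted p under 0.05). Libraries of the same number had correlations of -0.587 to 0.217 between their deviations from the group means. Only number 2 in DMD-Null and WT, at 0.217, exceeded the highest correlation with another number (0.142). No pairing by number was thus seen, but the split among the WT libraries could hide one.

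Dmd passed in mdx without WT 1 and WT 3 (-1.96), and in DMD-Null against mdx without them (-3.02) and with 8 libraries (-3.03). Without single replicates its changes were -1.51 to -0.63, -4.52 to -3.65 and -3.25 to -2.83. List calls (22, 23 and 7) were 5, 4 and 0 with an estimated correlation, 0 with fry for DMD-Null against mdx, and 19 to 23, 22 to 23 and 6 to 10 without single replicates. The dystrophin complex median in mdx (0.20, exact permutation adjusted p = 0.131) and the oxidative phosphorylation mean on log2(FPKM + 1) (-0.21, adjusted p = 0.0762, and -0.19, adjusted p = 0.114) lost the call. The latter mean ranged from -0.81 to -0.54 and -0.80 to -0.52 without single replicates and lost the call without any 1 mutant library. The fast-fibre mean in mdx ranged from -0.81 to -0.35 and passed without WT 2 (-0.81, exact permutation adjusted p = 0.0327). At this depth counting error is small, and 4 libraries per group limit what can be called.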

Other observations

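The counts of DMD-Null against mdx in 8 libraries with GC correction, the recovery of simulated changes as a test of group size, and the GC-corrected splits were chosen only after the result was seen.

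Of 17 genes of the unfolded protein and integrated stress responses, 9 rose and 2 fell in each mutant against WT (9 and 2 in mdx and 10 and 2 in DMD-Null adjusted over the list alone). The chaperones and folding factors Pdia4, Sdf2l1, Manf (0.86 in mdx) and Hspa5 (0.69) rose, whereas Ddit3, a pro-apoptotic factor, and Ppp1r15a, a regulatory phosphatase subunit, fell by 1.67 and 0.92. The list rose in mdx (camera adjusted p = 0.0379, adjusted p = 0.352 with an estimated correlation) and DMD-Null (camera adjusted p = 0.00963, adjusted p = 0.268 with an estimated correlation), and the mdx call ended without WT 1 and WT 3 (adjusted p = 0.0624) and under library totals (adjusted p = 0.055). Of 13 polarity genes 4 rose and 2 fell in mdx (4 and 3 adjusted over the list alone), and 3 rose and 1 fell in DMD-Null (3 and 2). The spindle factor Gpsm2 (1.84 in mdx) and the receptor Egfr (1.12 and 1.17) rose in both, and Mapk12 fell (-0.84 and -0.73). Of 15 Notch genes 5 rose and 3 fell in mdx and 4 rose in DMD-Null, also adjusted over the list alone, with the effector Rbpj at 1.21 in both. Neither list was called against WT (camera adjusted p = 0.579 and 0.469 in mdx, 0.715 and 0.564 in DMD-Null).

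Of 18 genes of atrophy and proteolysis, 2 rose in mdx (1 adjusted over the list alone) and 1 in DMD-Null (also over the list alone), with the lysosomal protease Ctsl at 1.23 and 1.13 in both (camera adjusted p = 0.635 and 0.767). The medians of the polarity and atrophy lists were below 0 (-0.14 and -0.04 in mdx, -0.18 and -0.04 in DMD-Null) although camera gave the upward direction, and above 0 under library totals. Of 24 calcium handling genes 7 fell and 1 rose in mdx, also adjusted over the list alone, and 6 fell and 1 rose in DMD-Null (7 and 1). The calcium release channel Ryr1 fell by 1.40 and 1.31, and Sln, which inhibits the calcium pump, rose by 3.47 and 3.37 (camera adjusted p = 0.249 and 0.0843). Of the clock genes, Nr1d1 fell in mdx (-1.78, edgeR adjusted p = 0.00703) and DMD-Null (-1.89, edgeR adjusted p = 0.00595), 1 of 14 tested. Its changes were smaller, -0.69 and -0.80, without WT 1 and WT 3 (edgeR adjusted p = 0.0248 and 0.0127). Of 13 immediate-early genes, Ier3 (0.40) and Atf3 (0.67) rose in mdx. In DMD-Null Atf3 (0.67) and Nr4a3 (1.05) rose, and Egr1 (-0.99) and Ier2 (-1.01) fell. Of 13 mitochondrially encoded genes, mt-Nd6 (-0.84 and -0.81) fell in both mutants, mt-Nd5 in mdx (-0.74) and mt-Nd3 in DMD-Null (-0.74). None of these 3 lists had a member past the threshold between DMD-Null and mdx. Of the 2 lymphocyte genes tested, Ighm fell in DMD-Null against WT (-1.46, edgeR adjusted p = 0.00732). The 1 keratinocyte gene tested, the 2 sex-linked genes and the substrain gene Nnt (357 to 1247 counts) did not pass in any comparison, and the Y-linked Ddx3y had 385 to 3855 counts in every library. Of 1297 gene terms, 112 were up and 61 down in mdx, 115 and 72 in DMD-Null, and 0 and 16 between them. Between the mutants these were 1 and 15 with GC-corrected offsets and 6 and 13 without WT 1 and WT 3. Against WT the same fits called more terms, 240 and 222 in mdx and 242 and 208 in DMD-Null. Collagen trimer (34 genes, camera adjusted p = 1.08e-07 and 4.88e-08) and phagosome (115 genes, camera adjusted p = 1.52e-07 and 1.99e-07) rose in both mutants.

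Few genes passed between DMD-Null and mdx. The WT libraries' spread in the shared fit is argued against as the whole reason for the tested genes, because the 8 libraries alone gave 4 genes. Genes at an unadjusted edgeR p under 0.05 rose from 120 to 354 there, so this spread may be part of the reason. The GC trend of DMD-Null 4 is also argued against as the whole reason, because the GC-corrected 8 libraries gave 4 genes (509 at an unadjusted p under 0.05). The bounds for both were set after the result was seen. In counts simulated for this comparison, 30.5% of 2-fold changes were recovered, so differences of that size may have gone undetected in the main fit. The simulated spread was estimated from all 12 libraries, WT included, so the recovery does not tell group size from the WT spread. Of 4-fold changes 95% were recovered, but with 200 changed genes, which eases the adjustment, and the 8.11-fold difference of Dmd, which lies under the filter, passed in the unfiltered fit of 8 libraries (edgeR adjusted p = 0.00922) but not of 12 (0.388), so larger differences may also have been missed. A likeness of both mutants remains a hypothesis, since 4 lists were lower and 3 higher in DMD-Null with the preset correlation, and 0 were called with an estimated one.

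Each comparison was refitted over the 35 splits of its 8 libraries. For mdx against WT, 1 split, the real one, reached 4001 genes and the highest other gave 0. A share of 1 in 35 is the smallest possible, so chance is made less likely but is not excluded. Splits that mix the groups put any difference between them into the spread, so the 0 does not tell genotype from other differences. For DMD-Null against mdx, 1 split, the real one, reached 2 genes and the highest other gave 1. The share of splits was again the smallest possible, but the margin is 1 gene, and the real count itself was 1 without mdx 3, mdx 4, DMD-Null 1, DMD-Null 2 or DMD-Null 4, so little rests on it. For DMD-Null against WT, 2 splits reached the real count of 3241, so chance could not be excluded. The other, which exchanges WT 2 and DMD-Null 4, gave 5553 and sets WT 4 and the 3 libraries with a high GC correlation (WT 1, WT 3 and DMD-Null 4) against WT 2 and DMD-Null 1 to 3, which points to a structure of the samples. With GC-corrected offsets 1 split, the real one, reached 4263 and the highest other gave 3440. Dmd counts do not go with an exchange of these libraries, at 3597 in WT 2 and 114 in DMD-Null 4, nor do the regeneration means, at 3.67 and 5.96 log2 CPM.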
